A study of Homo sapiens with 3 samples.

How the data were processed

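MicroRNA levels were measured with 3 one-colour Agilent human miRNA arrays of Y79 retinoblastoma cells, 1 hybridised with RNA of untreated control cells and 2 with RNA of cells treated with 20 uM curcumin for 48 h. Per the labels' protocols, total RNA was isolated with a kit that retains small RNA, and 100 ng per array was dephosphorylated and labelled by ligating a Cy3-carrying nucleotide to the 3' end of the RNA. The labels do not state whether the treated samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 3 arrays lay on 1 slide that was scanned in 1 pass, so slide and scan did not differ between groups, while the position on the slide did and cannot be told apart from the treatment.

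Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1 under its miRNA protocol, with a spatially fitted background subtracted from each spot, no multiplicative correction and no scaling between arrays. The deposited scanner files hold each spot's processed signal as an intensity on a linear scale, together with the raw mean and local background intensity of the spot and a total intensity per miRNA. The authors' deposited value table is on a log2 scale, and its making is not given in the sources used here. Setting it against the scanner files showed that each value equals log2 of the processed signal, with signals under 1 set to 1, minus 1 constant per array and minus the control array. Over spots well above background on both arrays the correlation was 0.99999 for both treated arrays (3024 spots for curcumin array 1 and 2915 for curcumin array 2), and the constants were 0.69 and 0.38. These constants lay near the log2 change of the 75th percentile over all spots, which was 0.69 and 0.38. The direction of the table is therefore treated minus control, its column medians were -0.69, -0.38 and 0 for curcumin arrays 1 and 2 and the control, and the reason for its centring stays unknown.

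For the main analysis, control spots and spots with outlier flags were left out, and the processed intensities of the remaining spots of a probe were averaged. A probe counted as detected on an array when over 50% of its spots were well above background, and a miRNA when any of its probes was. Each array was divided by its 75th percentile over the probes detected on all 3 arrays. A common floor was set at -4.18 on the log2 scale, the highest of the arrays' lowest scaled values among detected probes. Values were then converted to log2 and averaged over the probes of a miRNA that were detected on at least 1 array. Human miRNAs detected on the control array or on both treated arrays were tested, 246 in all. Treated and control were compared with limma 3.58.1 in R 4.3.3, using its linear model with empirical Bayes moderation, a two-sided test and Benjamini-Hochberg adjustment at 0.05. The model had 1 residual degree of freedom, from the treated arrays, and 0.964 prior degrees of freedom. The lone control array was assumed to vary like the treated ones. A miRNA counted as 2-fold changed when it lay at least 2-fold from the control in the same direction on both treated arrays, which involves no test. A miRNA below background on every array of a group has only a bound there. The brighter group's mean was then set against each dim array's lowest detected level, or the miRNA's own level where that was higher, and written as at least so many fold.

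Altogether 17 miRNA lists were fixed before the data were examined, along with the tests, the alternatives and the rule for naming miRNAs. The lists cover the miR-17~92 cluster, its paralogous clusters, the let-7 family, the cluster of miR-183, miR-96 and miR-182, miR-34 and p53-responsive miRNAs, the miR-15/16 family, neuronal and retinal miRNAs, the miR-200 family, miRNAs reported to respond to curcumin, onco- and hypoxia miRNAs, and the miR-29 and miR-30 families. They also cover embryonic stem cell clusters, the 14q32 cluster, markers of blood cells, markers of muscle, liver, stroma and endothelium, entries overlapping other RNA classes, and miRNAs listed as GC-rich and bright on this platform. The GC content of that last list, called the GC-rich list below, was not checked. The 15 lists with at least 3 tested members were compared with the remaining miRNAs by limma's camera at its preset correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether a list's members move one way on balance and does not compare them with other miRNAs. Named miRNAs were those with the largest changes (up to 10 each way), a fixed set of 16, up to 4 members per list, up to 5 bounds each way and the 5 brightest. Any other miRNA named was chosen after its values were seen. Arms of a precursor were paired by name, and correlations across pairs were tested with 100000 permutations.

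Positions are those of the array's probe targets in the file, on human build hg18 (NCBI build 36, per the file headers). Gene names came from a RefSeq table on GRCh38.p14, from which no coordinates were taken, and 59 of 79 named miRNAs matched a single RefSeq miRNA gene. Whether a miRNA lies in an exon or an intron of its host gene is not given in that table. miRNA names are those of the array's design and can be old.

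Alternatives covered the scaling (all probes, quantile, none, median), the background correction (normexp with an offset of 50 on the raw and local background intensities), the summary per miRNA (total intensity, brightest probe, deposited log ratios), the filter on dim probes, the floor (0.5 and 2 times), the outlier flags, limma's trend and robust options, and leaving out either treated array. On simulated data of 246 miRNAs with 50 draws and the same 3 arrays, limma called 80.1% of 2-fold and 90.8% of 4-fold changes at the adjusted threshold and 1.50% of unchanged miRNAs. A 9-member list shifted by -0.5 was called by camera in 90% of draws, and 0.714% of the other lists were. In the draws up to 30 miRNAs were changed by each size, errors were independent between miRNAs and every SD was above 0. In the data 11 tested miRNAs had the same floor value on both treated arrays, and miRNAs may move together, so these rates need not hold for the data. Viral miRNA probes, 76 on the array, served as a background reference and were not tested. The precision is limited by the number of arrays.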

Results

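The series addressed how curcumin, a polyphenol of turmeric, alters the microRNA profile of Y79 cells, an established retinoblastoma line that grows in suspension. It holds 3 arrays, 1 of untreated control cells and 2 of cells exposed to 20 uM curcumin for 48 h. Each array carried 2421 probes for 723 human and 76 viral miRNAs on 12784 spots. Spots well above background made up 24.6% on the control array, 29.6% on curcumin array 1 and 25.8% on curcumin array 2, and 0 spots were saturated. Human miRNAs detected numbered 230, 267 and 233 in the same order, and viral miRNAs, which serve as a background reference, 6, 13 and 11. Replicate spots of a probe varied by a median of 5.93%, 6.07% and 5.66%. Altogether 215 human miRNAs were detected on all 3 arrays and 449 on none. All log2 changes below are treated (n = 2 arrays) minus control (n = 1), so no spread could be measured within the control.

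Members of the miR-17~92 polycistron, miR-16 and the neuronal miR-124 were among the bright miRNAs of Y79 cells, although brightness also depends on the probe and does not rank amounts. By the scaled log2 level averaged over probes and the 3 arrays, miR-19b, miR-20a, miR-19a, miR-16 and miR-923 had the highest values. miR-923 was among them through the treated arrays, since in the control its level of 2.33 was below those of miR-124 (3.29), miR-17 (3.11), miR-15b (3.03) and miR-106b (2.99). On each array, whichever they were, the 5 miRNAs of highest signal held 35.5% of the human miRNA signal on the control array, 32.4% on curcumin array 1 and 32.4% on curcumin array 2. The mean spot intensity of miR-19b was 9068 in the control and 9159 and 7921 in the treated arrays, and that of miR-20a was 7442, 6964 and 6339. Both belong to the miR-17~92 cluster, whose target sites on the array lie on chromosome 13 within MIR17HG (miR-20a at 90801331 to 90801349, hg18). The spot intensity of miR-124 was 5657 in the control and 4706 and 4232 in the treated arrays. Members of the cluster of miR-183, miR-96 and miR-182, which is active in photoreceptors, were detected, among them miR-96 at 2102, 1744 and 1552. miR-204, abundant in pigment epithelium, and miR-199a-5p were not well above background on enough arrays to be tested, and miR-199a-3p is not on the array under that name.

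Against the untreated control, 12 miRNAs were at least 2-fold higher and 2 at least 2-fold lower on both curcumin arrays, and all 14 were detected on all 3 arrays. Among these 12, the highest values were those of miR-630 (log2 change 2.61, SE 0.18), miR-491-3p (1.83, SE 0.52), miR-923 (1.75, SE 0.06) and miR-22 (1.55, SE 0.07), a miRNA with antiproliferative activity in several tumour types. miR-188-5p (1.30), miR-32* (1.28), miR-424 (1.25), a relative of miR-16, miR-300 (1.15), miR-609 (1.14) and miR-483-5p (1.13), which is encoded within IGF2, came next among the 12. The other arm of the miR-32 precursor, miR-32, was at -0.43. miR-630, miR-188-5p and miR-483-5p belong to the fixed GC-rich list, of which 11 of 13 tested members lay above the control. That list was drawn up as following RNA quality and labelling, and neither this nor GC content was checked here. miR-923 matches ribosomal RNA. The lower pair was miR-135b (-2.46, SE 0.07) and miR-124* (-1.53, SE 0.09), the passenger strand of the neuronal miR-124. In spot intensity miR-22 went from 62.9 in the control to 235 and 191, miR-630 from 23.5 to 154 and 173, and miR-135b from 965 to 216 and 183. Other low values were those of miR-34c-5p (-1.01), miR-34b* (-0.94), miR-217 (-0.93, at the floor on both treated arrays), miR-216a (-0.93) and miR-181a (-0.91).

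**Figure D1:**
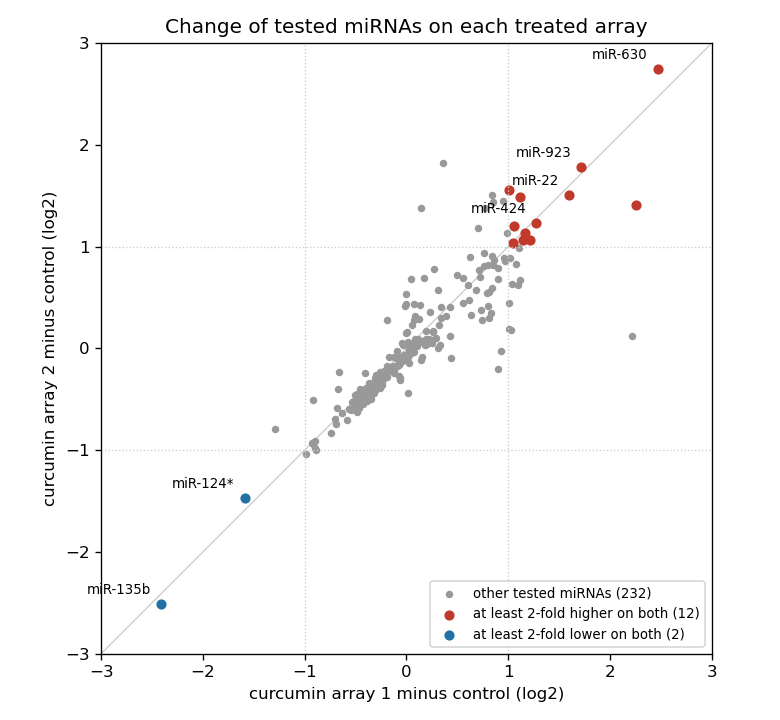
Log2 change of each of the 246 tested miRNAs on curcumin array 1 (horizontal axis) and curcumin array 2 (vertical axis) against the single control array, where each point is a miRNA and the diagonal marks equal change. Red points are the 12 miRNAs at least 2-fold higher and blue points the 2 at least 2-fold lower on both arrays, dotted lines mark 2-fold, and miR-630 and miR-135b lie at the upper and lower ends near the diagonal.

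Differences from the control were larger than those between the treated arrays. The SD of curcumin array 1 minus curcumin array 2 over the 246 miRNAs was 0.30 (95% bootstrap interval 0.23 to 0.37), against 0.62 and 0.63 for each treated array minus the control, and 4 miRNAs lay at least 2-fold apart between the treated arrays. With curcumin array 1 or curcumin array 2 taken as the lone array in place of the control, 1 and 2 miRNAs were 2-fold away from both others, against 14 for the control. Of the miRNAs detected on all arrays, 64.2% differed between the treated arrays by more than their spots' error, a measure that does not tell separate samples from repeat hybridisations of the same RNA. In limma with Benjamini-Hochberg adjustment 0 of 246 miRNAs passed, with 109 at an unadjusted p under 0.05 (36 higher and 73 lower). The lowest adjusted p was 0.0603, reached by 9 of the 14 miRNAs above, so all of them are values that did not pass.

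The counts depended on the processing. Against the main scaling, the median over miRNAs moved by -0.35 with the percentile over all probes, -0.33 with the deposited log ratios, -0.19 with quantile normalization, -0.13 with median scaling, 0.16 with the total intensity per miRNA and 0.20 with none. The count that passed ranged from 0 to 112 over the settings, and the 2-fold split of 12 higher and 2 lower became 4 and 10 with all probes, 6 and 16 with the deposited log ratios, 4 and 5 with quantile normalization, 6 and 6 with median scaling, 2 and 1 with normexp, 22 and 2 with no scaling, 29 and 4 with the total intensity and 19 and 5 with 0.5 times the floor. With curcumin array 2 alone (without curcumin array 1) 23 miRNAs lay at least 2-fold from the control, and with curcumin array 1 alone 25 did. miR-630, miR-923, miR-22, miR-424, miR-135b and miR-124* kept their direction under all 15 settings with a test, and miR-630 ranged from 1.23 to 2.81, miR-22 from 0.77 to 1.69 and miR-135b from -2.81 to -2.12. Dim miRNAs among the 12 came closer to the control: miR-300 was at 0.29 with 2 times the floor. With normexp miR-609 was at 0.26, miR-483-5p at 0.39 and miR-188-5p at 0.41.

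The target sites of the leading miRNAs are spread over the genome. On hg18, miR-22 lies on chromosome 17 from 1563958 to 1563976 within its host transcript MIR22HG, miR-135b on chromosome 1 from 203684112 to 203684134 in the region of LEMD1 and BLACAT1, and miR-630 on chromosome 15 from 70666677 to 70666693 within ARIH1. miR-491-3p lies on chromosome 9 from 20706155 to 20706174 within FOCAD, and miR-424 on chromosome X from 133508376 to 133508397 within MIR503HG. miR-124* lies on chromosome 20 from 61280316 to 61280332, where its precursor is 1 of several copies and no single RefSeq gene was matched.

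The miR-17 family of polycistrons, which promotes proliferation in many tumours, was lower on the curcumin arrays. In the miR-17~92 cluster all 9 tested members were below the control, with a median of -0.36 and values such as -0.65 for miR-18a, -0.44 for miR-19a, -0.43 for miR-17 and -0.40 for miR-20a. In the paralogous clusters of miR-106b, miR-93 and miR-25 and of miR-106a, miR-18b and miR-20b all 8 tested members were below it, with a median of -0.51 and values of -0.72 for miR-25, -0.58 for miR-93 and -0.53 for miR-18b. miR-106b* (-0.64) and miR-25* (-0.23) were at the floor on both treated arrays. Both were tested because they were detected in the control, so at that floor neither could lie above it. By camera both lists passed, with adjusted p = 0.0196 and 0.0177. By camera with an estimated correlation the adjusted p was 0.882 for both. That estimate rests on 1 residual degree of freedom and gave all 15 lists adjusted p between 0.882 and 0.914. It could hardly pass any list and does not decide the question. Adjusted over the list alone, 0 of 9 and 8 of 8 members passed, and over all tested miRNAs 0. The 8 include miR-106b* and miR-25*, whose SD between the treated arrays was 0 because of the floor. Of all 246 tested miRNAs, 109 had an unadjusted p under 0.05 by limma. Some members, such as miR-17, miR-20a, miR-106a and miR-106b, are close in sequence, and cross-hybridisation between them was not checked. The call ended under 7 and 5 of 15 settings, among them all probes and quantile normalization, while the medians stayed below 0 in each, from -0.71 to -0.15 and from -0.90 to -0.31. A median below 0 depends on the scale factor of each array and does not compare the lists with other miRNAs. The gap between both lists together and the other tested miRNAs was -0.45 in the main analysis and -0.15 with quantile normalization.

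The 14q32 cluster, an imprinted domain with a large miRNA array, was higher on the curcumin arrays in a call that depended in part on the filter. Of 65 members on the array 10 were tested, with a median of 0.48 and camera adjusted p = 0.0196. The preset correlation of 0.01 treats these clustered members as nearly independent, so this p-value is likely too small. By fry the adjusted p was 0.141. With an estimated correlation, which could hardly pass any list here, camera gave adjusted p = 0.882. All 10 were above the control, but 4 of them were tested because they were detected on both treated arrays and stood at the floor in the control, so they could not lie below it. With miRNAs detected on all 3 arrays the median was 0.60 and the call ended (adjusted p = 0.113). miR-300 (1.15) and miR-485-3p (1.04) passed adjusted over the list alone, 2 of 10, and 0 passed over all tested miRNAs. miR-494 was at 0.61. miR-381 was not well above background in the control and was at least 1.54-fold higher. The members were dim, with spot intensities of 66.3, 165 and 151 for miR-485-3p and 17.9, 50.3 and 45.4 for miR-300, and over the 449 human miRNAs detected on no array the median intensity was higher by 0.553 and 0.421 on the treated arrays. The call ended under 5 of 15 settings, and the median was 0.31 without curcumin array 2, 0.04 with 2 times the floor and 1.17 with the total intensity. The GC-rich list, drawn up as following RNA quality and labelling, moved the same way without passing (11 of 13 above the control, median 0.29, camera adjusted p = 0.0659), and passed under 4 of 15 settings. Both lists hold miR-494 and miR-134, the latter at the floor in the control, so the lists are not independent.

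**Figure D2:**
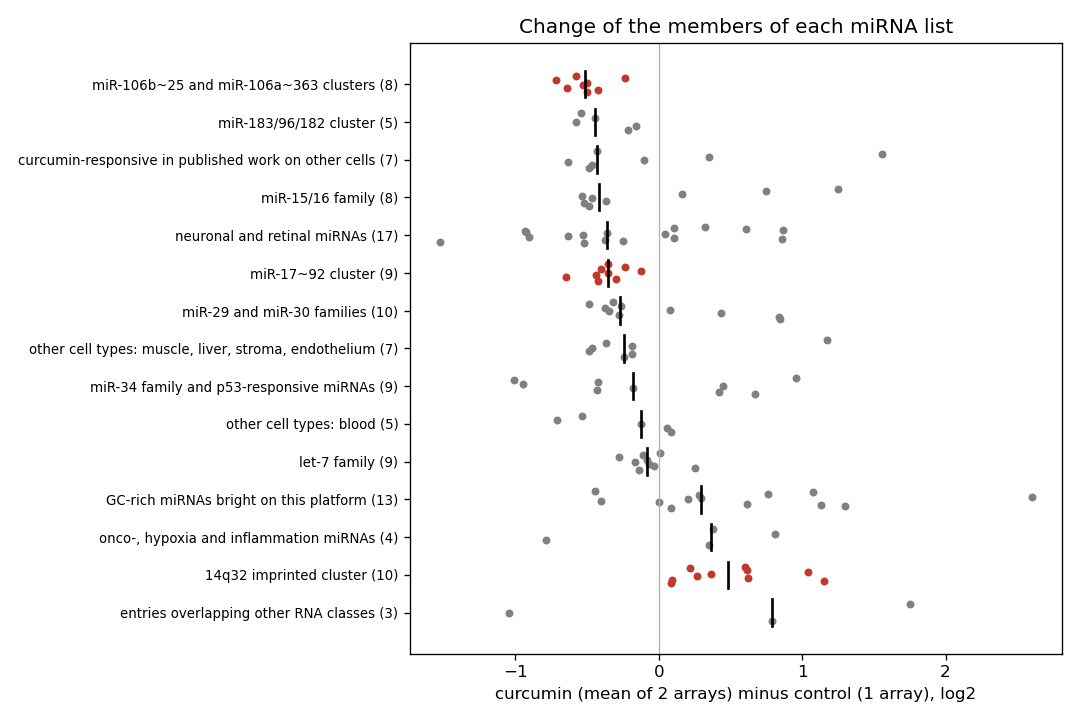
Log2 change of the tested members of each miRNA list with at least 3 of them, as the mean of 2 curcumin arrays minus the control array (horizontal axis), with the number of members in brackets. Each point is a miRNA, black bars are list medians, and red marks the 3 lists that passed camera at its preset correlation, which lie at medians of -0.51, -0.36 and 0.48. The preset treats the members of a list as nearly independent. With an estimated correlation, which rests on 1 residual degree of freedom and could hardly pass any list, none of them passed.

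Neuronal and retinal miRNAs went both ways. Of 17 tested, 8 were lower and 3 higher adjusted over the list alone, and 0 passed over all tested miRNAs. The lower ones included miR-124* (-1.53), miR-181a (-0.91), miR-216a (-0.93) and miR-124 (-0.52), along with miR-217 (-0.93), which was at the floor on both treated arrays. The higher ones were miR-218, miR-7 and miR-9*, chosen after their values were seen, at 0.86, 0.61 and 0.32, while miR-9 itself was at 0.11 and turned to -0.25 with all probes. The list median was -0.36, with camera adjusted p = 0.346. In the photoreceptor cluster of miR-183, miR-96 and miR-182 all 5 tested members were below the control, with a median of -0.45 and camera adjusted p = 0.150. miR-183 (-0.58) and miR-96 (-0.54) passed adjusted over the list alone. miR-183* was at -0.45, and miR-182 (-0.21) was at 0.01 without curcumin array 2. Counts adjusted over a list alone, here and below, are lenient and were not corrected for the number of lists. Among all 246 tested miRNAs, 109 had an unadjusted p under 0.05 by limma, so such counts do not set a list apart.

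The miR-34 family and other p53-responsive miRNAs had no common direction. miR-34c-5p (-1.01), miR-34b* (-0.94) and miR-34a (-0.43) were lower and miR-605 (0.95) and miR-194 (0.42, at the floor in the control) higher adjusted over the list alone, where 2 of 9 were higher and 4 lower. miR-192, at 0.67, did not pass, and camera gave adjusted p = 0.730. The list median of -0.18 turned to 0.02 with no scaling and 0.03 with the total intensity, and was -0.07 without curcumin array 2 and -0.29 without curcumin array 1. The miR-15/16 family, which targets BCL2 and cell cycle genes, split by precursor. miR-15a (-0.48), miR-16 (-0.46) and miR-15a* (-0.52, at the floor on both treated arrays) were lower and miR-424 (1.25) and miR-195* (0.74) higher, each passing adjusted over the list alone (2 higher and 3 lower of 8), with miR-16-2* at -0.54 and camera adjusted p = 0.730. With the total intensity miR-15a* was at 0.06. In both lists 0 members passed over all tested miRNAs.

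Of the miRNAs reported to respond to curcumin in other cells, 7 were tested and went both ways. miR-22 (1.55) and miR-21 (0.35) were higher and miR-181b (-0.64), miR-15a (-0.48), miR-16 (-0.46) and miR-34a (-0.43) lower, 2 and 4 of 7 adjusted over the list alone, and 0 over all tested miRNAs. The camera adjusted p was 0.604. miR-22 entered this list with a report on Y79 cells in view, so it is not independent evidence. Among onco-, hypoxia and inflammation miRNAs, miR-221 (0.81) and miR-21 were higher, miR-222 was at least 1.30-fold higher, and miR-210, a marker of hypoxia, was lower (-0.78). These were 3 higher and 1 lower of 4 adjusted over the list alone, 0 over all tested miRNAs, with camera adjusted p = 0.266. With all probes miR-21 was at -0.0019.

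The remaining lists did not pass. In the let-7 family, associated with differentiation, 7 of 9 members lay below the control and 0 passed adjusted over the list alone. Values were -0.28 for let-7g, -0.17 for let-7e, -0.14 for let-7a and 0.25 for let-7b, with a median of -0.09 that turned to 0.12 with no scaling and 0.07 with the total intensity (camera adjusted p = 0.586). let-7a was at 0.07 and let-7e at 0.03 with no scaling, and let-7b was at -0.10 with all probes. Without curcumin array 2 let-7b was at 0.07, let-7e at -0.07 and the median at -0.06, and without curcumin array 1 they were at 0.44, -0.27 and -0.12. In the miR-29 and miR-30 families miR-29a (0.84) and miR-29b (0.84) were above the control and miR-30e (-0.49) below it, with miR-30a at 0.43 (0.17 without curcumin array 2, 0.70 without curcumin array 1 and 0 with 2 times the floor). Of 10 members, 1 (miR-29b) passed adjusted over the list alone, and the list's median of -0.27 and its mean of 0.01 differed in sign (adjusted p = 0.729, direction down). Of the epithelial miR-200 family only miR-141 was tested (0.63), and of the embryonic stem cell clusters 0 members were.

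Markers of other cell types did not pass as lists. Of 5 blood miRNAs, miR-486-5p (-0.54) was lower adjusted over the list alone, and miR-486-3p was at -0.71, miR-451 at -0.13 and miR-142-3p at 0.09 (camera adjusted p = 0.729). The list median of -0.13 turned to 0.08 with no scaling, as did miR-451, and miR-142-3p was at -0.26 with all probes. Of 7 markers of muscle, liver, stroma and endothelium, 6 lay below the control and 1 (miR-206) above it, with a median of -0.25, and 0 passed adjusted over the list alone, with miR-206 at 1.17, miR-133a at -0.48, miR-133b at -0.47 and miR-145 at -0.37 (adjusted p = 0.266). Among entries that overlap other RNA classes, miR-923, which matches ribosomal RNA, and miR-801 (0.79), which matches a small nuclear RNA, were higher adjusted over the list alone, 2 of 3, while miR-886-3p, which matches a vault-like RNA, was at -1.04 (adjusted p = 0.266). The spot intensity of miR-923 was 2408 in the control and 7770 and 7149 in the treated arrays. Members of the GC-rich list, drawn up as following RNA quality and labelling, lay above the control in 11 of 13 cases, led by miR-630 (2.61), miR-188-5p (1.30), miR-483-5p (1.13) and miR-765 (1.07). Their median was 0.29 with adjusted p = 0.0659, and 0 passed adjusted over the list alone. Over all tested miRNAs 0 members of these lists passed.

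Some miRNAs were above background in 1 group only. Of 16 detected on both treated arrays and not in the control, miR-885-3p had the largest bound, at least 2.13-fold higher (adjusted p = 0.432), with spot intensities of 21.5 and 75.4 on the treated arrays. Without curcumin array 2 its log2 change was 0.36, and with outlier spots kept it turned to -0.54. miR-381 was at least 1.54-fold, miR-640 at least 1.47-fold, miR-339-3p at least 1.36-fold and miR-194 at least 1.33-fold higher. The 5 detected in the control and on neither treated array were miR-514, at least 1.86-fold lower with curcumin (adjusted p = 0.0603), miR-181a* at least 1.54-fold, miR-95 at least 1.41-fold, miR-25* at least 1.35-fold and miR-191* at least 1.31-fold lower. Adjusted p ranged from 0.0603 to 0.432 over these 10.

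The strands of a precursor tended to change alike. Across 47 pairs of arms with both tested, the log2 changes correlated with Pearson's r = 0.55 (permutation p = 9.0e-05, Benjamini-Hochberg adjusted 9.0e-05 over 2 relations) and Spearman's rho = 0.58 (permutation p = 3.0e-05, adjusted 6.0e-05), and 35 pairs had the same sign. The correlation is across miRNAs, which are not independent replicates, and all pairs share the 1 control array. miR-124 and miR-124* (-0.52 and -1.53) and miR-183 and miR-183* (-0.58 and -0.45) went together. In contrast, miR-32 and miR-32* (-0.43 and 1.28) and miR-1228 and miR-1228* (-0.32 and 1.20) differed in sign on both treated arrays. miR-34b and miR-34b* (0.45 and -0.94) did so on curcumin array 1 only, where miR-34b was at 0.93, against -0.03 on curcumin array 2.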

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

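The tests of the background level reported here were chosen after the result was seen, apart from the test of the viral probes. Some viral miRNA probes and a fly control probe, which lay outside the comparison, were brighter on the treated arrays. On curcumin array 1 there were 13 viral miRNAs detected and on curcumin array 2 there were 11, against 6 on the control array. Of the 6 viral miRNAs detected on all 3 arrays, 5 were brighter on both treated arrays, among them the Epstein-Barr virus entries BART12 (intensity 334, 439 and 677) and BART16 (110.6, 230.3 and 328). The fly control probe dmr_285 had a mean intensity of 4.64 in the control, 28.0 on curcumin array 1 and 12.5 on curcumin array 2.

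The pattern weighed is that dim human probes and some viral probes were brighter on the treated arrays. Over the 449 human miRNAs detected on no array, the median intensity was higher by 0.553 and 0.421. A uniform rise of the background left after subtraction is argued against, since the negative-control spots were lower on both treated arrays. The differences were -0.691 (SE 0.270) and -1.51 (SE 0.293), with SEs over spots and not over arrays. These are processed intensities, so a rise that the background subtraction removed would not show in them. Added non-specific signal on miRNA probes cannot be told apart from an effect of the treatment, because the median over all 76 viral miRNAs moved by 0.275 (SE 0.185) on curcumin array 1 and by -0.170 (SE 0.229) on curcumin array 2, with 46 and 36 of them above the control. The position on the slide and the treatment stay open as untested explanations.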

How the results depend on the processing

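One setting, leaving out miRNAs at the floor on the control or on both treated arrays, was chosen after the data were seen. No paired analysis was possible because the control carries no replicate number, slide as a block was not run because all arrays lay on 1 slide, and leaving out a treated array left no residual degrees of freedom, so counts of passing miRNAs, list tests and the agreement of the treated arrays have no value there. Signal over background limited the dim miRNAs: 14 tested ones were at the floor in the control and 11 on both treated arrays.

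By limma, 0 miRNAs passed in the main analysis, with no scaling, normexp, brightest probe, no filter, 2 times the floor or outlier spots kept. The count was 112 (12 higher, 100 lower) with the percentile over all probes, 99 (16, 83) with quantile normalization, 92 (21, 71) with median scaling, 35 (25, 10) with the total intensity, 57 (21, 36) with the deposited log ratios, 66 (50, 16) with miRNAs detected on all 3 arrays, 96 (58, 38) with 0.5 times the floor, 32 (14, 18) with the trend option, 34 (22, 12) with the robust option and 55 (43, 12) without floor-level miRNAs. The main adjusted p of 0.0603 lay close to the threshold, and the cause of these shifts in the count was not tested. The 11 miRNAs at the floor on both treated arrays had an SD of 0 there, which enters limma's moderation. The prior degrees of freedom were 0.964 in the main analysis, 4.04 with 0.5 times the floor and 0.415 with 2 times the floor. They were infinite without floor-level miRNAs and with miRNAs detected on all 3 arrays. With all probes they were 0.651 while 112 passed, so a low value did not always go with 0 passing. The 2-fold count of 14 was 9 with quantile normalization, 24 with no scaling, 3 with normexp, 33 with the total intensity, 22 with the deposited log ratios, 24 with 0.5 times the floor, and 23 to 25 without 1 treated array, where 1 array instead of 2 has to pass.

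Against 3 lists in the main analysis, 1 passed with all probes, 0 with quantile normalization, 1 with no scaling, 0 with normexp, 1 with miRNAs detected on all 3 arrays (GC-rich, adjusted p = 0.0144), 1 with 2 times the floor, and 0 with an estimated correlation. The version with an estimated correlation rests on 1 residual degree of freedom and could hardly pass any list. By fry, which tests a list against no change and not against other miRNAs, 0 passed. The SD between the treated arrays, 0.30, was 0.15 with normexp and 0.22 with 2 times the floor. Viral miRNAs detected on the control numbered 10 by the scanner's own call instead of 6. The guide and star correlation of 0.55 ranged from 0.36 to 0.59, with its highest permutation p at 0.0421.

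Directions turned as follows, and the cause was not tested. With all probes miR-21 was at -0.0019, miR-9 at -0.25, let-7b at -0.098 and miR-142-3p at -0.26. miR-9 was at -0.086 with quantile normalization, -0.025 with median scaling and -0.23 with the deposited log ratios, where let-7b was at -0.085 and miR-142-3p at -0.26. miR-142-3p was at -0.044 with median scaling. With no scaling let-7a was at 0.067, let-7e at 0.034, miR-451 at 0.075, and the medians were 0.12 for let-7, 0.024 for miR-34 and 0.075 for blood. With the total intensity let-7a was at 0.017, miR-15a* at 0.064, and the medians were 0.070 for let-7 and 0.026 for miR-34. miR-885-3p was at -0.54 with outlier spots kept, and miR-182 ranged from -0.44 to 0.012 without 1 treated array. Of the other values of named miRNAs, 949 kept direction and side and 328 passed where the main value had not. Of the list medians 229 kept both, 17 no longer passed and 4 passed only in the alternative.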

Other observations

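The tests on the scaling and the gap between the miR-17 family and the other miRNAs were chosen after the result was seen, while the remaining tests on that family and those on neighbouring miRNAs were fixed before their results. Neighbouring pairs named here were chosen after their values were seen. miR-221 (0.81) and its neighbour miR-222 on chromosome X were both above the control, while miR-27a (0.10), miR-23a (0.11, with 0.16 and 0.06 on the single arrays) and miR-24 (-0.24) on chromosome 19 were closer to 0. Members of the chromosome X group around miR-500*, miR-362-5p, miR-660 and miR-502-5p stood at 0.12, 0.07, 0.12 and 0.01 (0.20, 0.11, 0.16 and 0.03 on curcumin array 1 and 0.05, 0.03, 0.07 and -0.01 on curcumin array 2), whereas miR-188-5p of the same group was at 1.30. Neighbours also went apart, such as miR-206 and miR-133b (1.17 and -0.47). miR-29c and miR-29b (-0.28 and 0.84) differed too, but miR-29b matched no single RefSeq gene, so its signal need not come from that site.

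The hypothesis that miRNAs transcribed together change together was tested on 43 pairs of neighbours from different precursors within 10 kb. Their log2 changes differed by a mean of 0.36, against 0.66 after random pairing (one-sided permutation p = 3.0e-05 over 100000 permutations). Without the miR-17 family, 37 pairs differed by 0.40, with a permutation p of 0.00062. Co-transcription would give such a pattern, although cross-hybridisation of neighbours with similar sequence was not checked, and the pairs share the 1 control array. The random pairing was not matched on brightness, with which the changes varied, and some neighbours were at the floor in 1 group. Each miRNA was placed at the position given for its probes, so the signal of a miRNA with several gene copies may come from elsewhere.

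The miR-17 family clusters were lower on the treated arrays, with a median of -0.43 over 17 members. Bright miRNAs were lower in general, at a median of -0.30 over the brightest 62 against 0.07 over the dimmest 62. The family median lay at percentile 1.23 of 10000 random lists matched on brightness, whose medians centred on -0.14 (95% range -0.38 to 0.22). For the 17 members pooled over the clusters, that percentile went against a trend with brightness alone. However, the random lists draw miRNAs singly, while members of a cluster can change together. The range is then likely too narrow, and a trend with brightness is not excluded. The miR-17~92 cluster alone, with a median of -0.36, lay within the range of these 17-member lists, and no matched lists were drawn for it. The choice of scaling stays open. The highest median over the scaling, background and summary settings was -0.22, but a median below 0 depends on the scale factor of each array and does not compare the family with other miRNAs, so that bound was set on the wrong value. The gap to the median of the other tested miRNAs was -0.45 (SE 0.06 over miRNAs) in the main analysis and -0.15 (SE 0.06) with quantile normalization, where the smaller gap came with camera adjusted p = 0.138 and 0.108 and both calls ended. Cross-hybridisation among those members that are close in sequence, which was not checked, the slide position and an effect of curcumin stay open.

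The split of 2-fold changes, 12 higher and 2 lower, became 6 and 16 with the deposited log ratios. A general fall of miRNA signal on the treated arrays stays open: with no scaling the median change over miRNAs detected on all arrays was 0.23 and 0.07, with a mean of 0.15 against an SE of 0.15 from the SD between the treated arrays, and labelling and hybridisation of single arrays enter these values. A candidate explanation is that the percentile over all probes follows dim probes: it was higher on the treated arrays by 0.68 and 0.43, and its change exceeded the median change of detected miRNAs by at least 0.368 on the log2 scale. This gap is nearly the same quantity as the shift of -0.35 between the main scaling and that over all probes. It describes the difference and is no separate test of the explanation. Which scaling is nearer to the amounts in the cells stays open, since no spike-in was used, per the file headers.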
